A study of Mus musculus with 8 samples.

How the data were processed

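MicroRNA (miRNA) counts were analysed in liver from male C57BL/6J mice, an inbred laboratory strain, that were 10 to 11 weeks old and ate either normal chow or a high-fructose diet (HFrD) for 2 weeks, with 4 samples per diet. Per the labels, HFrD supplied 10% of its calories as fat, 70% as carbohydrate and 20% as protein. Such shares are not recorded here for the chow, so the diets may differ in more than fructose. The labels number the samples as replicates and do not state that each came from its own mouse, so the p-values measure the spread between these samples. Total RNA was taken with TRIzol, per the labels' protocols. The same protocol text goes on to depletion of ribosomal RNA and a stranded total RNA library on an Illumina NovaSeq instrument. The step that selected small RNA is not given in the sources used here, so its bias towards some sequences is not known.

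The main values are raw tag counts per mature miRNA, deposited as whole numbers for each sample, per the file headers. Reads were trimmed and aligned with tools that include cutadapt 1.9.2 and Novoalign 3.02.12 against the mouse build mm10, per the submitters' processing notes. The miRNA reference release, the rule for reads that match several miRNAs and the tool that predicted further miRNAs are not given in the sources used here. The authors also deposited normalized values, treated here as a score, in which each raw count had been divided by a number that is constant within a library and then rounded. That divisor ran from 4.21 to 6.19, and how the authors derived it is not given in the sources used here. Normalized values recomputed with it differed from the deposited score by at most 0.626. All value columns were matched to samples through the sample descriptions in the labels.

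The count table had 484 entries, because a miRNA with several precursor genes was entered once for each of them with the same counts. Entries were merged by mature sequence into 443 sequences, of which 377 had an established name and 66 had been predicted by the authors. Because 11 of these sequences carried more than 1 name, members of such near-identical groups cannot be separated. The smallest value in the table was 2, and 1252 of the 3544 cells, 35.3%, were blank. Blank cells were read as 0, and no upper limit was computed for them, since values below 2 were left out of the table. Library totals ranged from 1120040 to 1638040 counts. A single count was worth between 0.610 and 0.893 on the counts-per-million (CPM) scale of its library total, and intervals from counting alone would understate the error, since reads without molecular identifiers are not independent molecules.

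The diets were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with diet as the only term, trimmed mean of M-values (TMM) factors and the filterByExpr filter at its minimum count of 10. The test was two-sided and p-values were adjusted by Benjamini and Hochberg's method over the miRNAs tested, with a threshold of 0.05. CPM values are given over the TMM-scaled library size as mean ± SD. The composition measures and the pooled values of predicted or clustered sequences use library totals instead. Log2 fold changes are HFrD against chow with their standard errors (SE). A comparison of a single value used the exact two-sided permutation test over the 70 assignments of 8 samples to 4 and 4, whose smallest p is 0.0286. Lists of miRNAs were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, where at least 3 members had passed the filter. Medians of lists are of the differences in mean log2 CPM on that scale. For rare miRNAs these can differ from edgeR's log2 fold changes in either direction, as for miR-300-3p (0.72 against 0.43 in edgeR). The ratio of the 5p to the 3p arm of a hairpin, log2 of CPM plus 0.5, was tested with limma. Precursor positions came from GENCODE M21 on GRCm38, the assembly behind mm10, and mature sequences were searched for exact sense matches in its transcripts. After the data were seen, they were also searched on both strands of its 356 ribosomal RNA transcripts, because the annotated copy of 18S ribosomal RNA is given there on the opposite strand. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

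Before the data were examined, the design, the alternatives, 21 lists of miRNAs and a rule for naming miRNAs were fixed. The lists were hepatocyte, lipid and sterol metabolism, insulin and glucose metabolism, fibrosis and inflammation in fatty liver, hypoxia and oxidative stress, and p53-regulated miRNAs. Lists for other cells the tissue could hold were myeloid, lymphoid, erythroid, endothelial, stellate and fibroblast, biliary, muscle, and pancreas and neuroendocrine. The families and clusters were let-7, miR-29, miR-30, miR-378, miR-15 and miR-16, the miR-17 to miR-92 clusters and the imprinted Dlk1-Dio3 cluster. Lists share members, for instance miR-122-5p in the hepatocyte and lipid lists. The naming rule took both arms of miR-22, the 10 miRNAs with the smallest p in each direction, the 5 most abundant, the 2 to 4 most abundant members of each list with every member past the threshold, and, where no arm ratio passed, the 3 with the smallest p.

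The alternatives were other scaling factors (relative log expression, library totals, upper quartile, TMM without the most abundant miRNA), no filter, a stricter filter of 10 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, robust estimation, limma on the authors' normalized score (log2 of the value plus 1), the replicate number as a block, and each library left out in turn. For the lists they also included an estimated correlation and fry, and for the arm ratios a pseudocount of 2 and a mean trend. After the data were seen, fits without the predicted sequences, with an entry for each name, with blank cells as 1 count, and with limma on log2 CPM with and without a correction for GC content were added.

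The test was checked on simulated counts for the 170 miRNAs of this comparison, with 60 changed in each of 20 simulations. It recovered 63.5% of those changed 1.5-fold, 93.3% of those changed 2-fold and 100% of those changed 3-fold, and 2.3% of its calls were false. With fewer miRNAs changed, the adjusted threshold would be stricter and recovery lower, and the data gave 10 calls. In simulated arm ratios over 21 hairpins, 99.2% of 3-fold changes were recovered and 12.5% of the calls were false, above the 5% aimed at. Simulated lists whose members were raised 1.5-fold were recovered in 95% of 20 simulations. There all members rose together and each miRNA was drawn independently. Correlations estimated within the real lists reached 0.44, so recovery in these may be lower.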

Results

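Mature miRNAs were counted in 8 liver samples, 4 from mice on chow and 4 from mice on HFrD for 2 weeks. Chow replicates 1 to 4 held 1231070, 1223470, 1339840 and 1256860 counts, and HFrD replicates 1 to 4 held 1385860, 1120040, 1638040 and 1273860 counts. A few miRNAs made up most of these counts. The hepatocyte-enriched miR-148a-3p held 38.8% of the counts, followed by miR-21a-5p with 18.3%, the liver-specific miR-122-5p with 15.1%, miR-192-5p with 9.08% and miR-30a-5p with 4.36%. The 10 most abundant miRNAs held 94.4% ± 0.101 (SD, n = 4) of the counts in chow and 94.2% ± 0.301 (SD, n = 4) in HFrD. Of 443 mature sequences, 170 passed the filter and held 99.96% of all counts. Counts of replicates differed by more than sampling noise in each pair within a diet (chi-square per degree of freedom from 6.60 to 248), a comparison with counting error alone.

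The comparison of diets asks which liver miRNAs differ between HFrD and chow, with miR-22-5p named in the study's title. An effect of fructose cannot be told apart here from other differences between the diets. In HFrD, 6 miRNAs were lower and 4 were higher. The fall was 1.72-fold for miR-22-5p, 1.71-fold for miR-881-3p and 1.55-fold for miR-122-3p, the passenger arm of the hepatocyte miRNA miR-122. It was 1.38-fold for miR-30a-5p, 1.37-fold for miR-27b-3p, a regulator of lipid-metabolism genes, and 1.35-fold for miR-126a-3p, a miRNA of endothelial cells. The rise was 1.65-fold for miR-484, 1.80-fold for miR-671-3p, 1.95-fold for miR-12182-3p and 5.49-fold for a sequence that the authors predicted as a miRNA of chromosome 9 and that also lies within 18S ribosomal RNA.

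miR-22-5p (AGUUCUUCAGUGGCAAGCUUUA) was measured at 54.1 ± 12.3 CPM (SD, n = 4) in chow and 31.6 ± 7.28 CPM (SD, n = 4) in HFrD. Its log2 fold change was −0.78 (SE 0.21, adjusted p = 0.0374, edgeR). The counts behind these values were 86, 70, 61 and 46 in chow and 36, 43, 61 and 37 in HFrD. All 4 HFrD samples lay below all 4 chow samples in TMM-scaled CPM (exact permutation p = 0.0286, the smallest that 4 against 4 samples can give). This separation depended on the scaling, as TMM factors averaged 0.959 in chow and 1.05 in HFrD (exact permutation p = 0.0571, unadjusted). Over library totals, chow replicate 4 (46 of 1256860 counts) lay below HFrD replicate 2 (43 of 1120040) and HFrD replicate 3 (61 of 1638040). The other arm, miR-22-3p, is the guide strand and was far more abundant, with 4495 ± 296 CPM (SD, n = 4) in chow and 3934 ± 175 CPM (SD, n = 4) in HFrD. Its log2 fold change of −0.19 (SE 0.083) did not pass the threshold (adjusted p = 0.164, edgeR). The groups of miR-22-3p did not overlap in TMM-scaled CPM either (exact permutation p = 0.0286). Over library totals they did, with chow replicate 4 (4781 of 1256860 counts) below all 4 HFrD samples. With library totals its log2 fold change was −0.07 (adjusted p = 0.652, edgeR). Both arms come from Mir22 on chromosome 11, at 75463716 to 75463810 on the plus strand of GRCm38, within an exon of the non-coding host gene Mir22hg and of a transcript of Tlcd2. The call for miR-22-5p was lost, with the direction kept, when 1 of 4 libraries was left out: adjusted p was 0.101 without chow replicate 1, 0.128 without chow replicate 2, 0.0586 without HFrD replicate 1 and 0.0910 without HFrD replicate 4. It was also lost with DESeq2 (adjusted p = 0.0502), with upper quartile factors (0.154) and with limma on the authors' normalized score (0.105), out of a range from 0.0102 to 0.154 over the 24 alternatives.

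Among the other miRNAs that fell, miR-122-3p went from 216 ± 32.5 to 139 ± 5.28 CPM (SD, n = 4 each; log2 fold change −0.64, SE 0.12, adjusted p = 0.0109). Its precursor Mir122 lies on chromosome 18 at 65248861 to 65248926, in an exon of a long non-coding RNA gene. The guide arm miR-122-5p was measured at 164715 ± 6310 CPM in chow and 137266 ± 19232 CPM in HFrD, a log2 fold change of −0.26 that did not pass (SE 0.097, adjusted p = 0.0985, edgeR). It passed under 1 of 24 alternatives, with adjusted p from 0.0132 to 0.547 over them. miR-27b-3p went from 8522 ± 1287 to 6227 ± 128 CPM (log2 fold change −0.45, SE 0.099, adjusted p = 0.0123). Mir27b lies on chromosome 13 at 63300712 to 63300784, in an exon of 2010111I01Rik and opposite an intron of Fancc. miR-126a-3p went from 8238 ± 1115 to 6115 ± 370 CPM (log2 fold change −0.43, SE 0.098, adjusted p = 0.0123), and its gene lies on chromosome 2 at 26591357 to 26591429 within Egfl7, a gene of endothelial cells. Because Mir126b is annotated on the opposite strand there, the 2 precursors overlap. The other arm, miR-126a-5p, which the naming rule did not take, was at −0.12 (SE 0.11, adjusted p = 0.504, edgeR). miR-881-3p went from 113 ± 18 to 65.6 ± 13.7 CPM (log2 fold change −0.77, SE 0.16, adjusted p = 0.0123), from an intergenic precursor on chromosome X at 66801944 to 66802021 on the minus strand. miR-30a-5p went from 51192 ± 12922 to 37101 ± 3430 CPM (log2 fold change −0.46, SE 0.13, adjusted p = 0.0423), from an intergenic precursor on chromosome 1 at 23272269 to 23272339. Its other arm, miR-30a-3p, also outside the naming rule, was at 0.21 (SE 0.30, adjusted p = 0.677, edgeR). Chow replicate 4 stood highest for miR-30a-5p, at 70098 CPM against 41619 to 48561 CPM in the other chow libraries, and without it the log2 fold change was −0.30 (adjusted p = 0.0561). The call for miR-30a-5p also ended without chow replicate 2 (adjusted p = 0.127) and without HFrD replicates 1, 2 and 4 (0.0521, 0.0935 and 0.0970). Those for miR-881-3p and miR-27b-3p ended without chow replicate 2 alone (adjusted p = 0.0713 for both), and that for miR-126a-3p without chow replicate 2 (0.0844) or HFrD replicate 4 (0.0643). Over all alternatives, adjusted p ran up to 0.0747 for miR-122-3p, 0.0755 for miR-881-3p, 0.154 for miR-27b-3p, 0.175 for miR-126a-3p and 0.252 for miR-30a-5p.

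Among the miRNAs that rose, miR-484 (UCAGGCUCAGUCCCCUCCCGAU) went from 45.8 ± 12.8 to 76.2 ± 3.17 CPM (SD, n = 4 each; log2 fold change 0.73, SE 0.18, adjusted p = 0.0212). Its gene lies on chromosome 16 at 14159626 to 14159692, opposite an intron of Marf1. miR-12182-3p went from 23.8 ± 7.07 to 46.6 ± 11.8 CPM (log2 fold change 0.96, SE 0.24, adjusted p = 0.0212), with overlapping groups, and its precursor was not located in the annotation used. miR-671-3p (UCCGGUUCUCAGGGCUCCACC) went from 11.5 ± 2.06 to 20.8 ± 2.11 CPM (log2 fold change 0.85, SE 0.24, adjusted p = 0.0423). Mir671 lies on chromosome 5 at 24592114 to 24592211, in an exon of Chpf2 and opposite an exon of Smarcd3. The predicted sequence GAGGCCCUGUAAUUGGAAUGAGU went from 4.73 ± 1.82 to 27.7 ± 23.2 CPM (log2 fold change 2.46, SE 0.55, adjusted p = 0.0123), with counts of 7, 8, 5 and 3 in chow and 25, 71, 13 and 34 in HFrD. All 23 of its bases match positions 551 to 573 of an annotated copy of 18S ribosomal RNA (Rn18s-rs5, chromosome 17, 39846354 to 39848202), so its counts are not shown to come from a miRNA. Of the 10 changed miRNAs, miR-484 and miR-671-3p have the highest GC contents, 63.6% and 66.7%, and after a correction for GC content their log2 fold changes of 0.76 (SE 0.18) and 0.79 (SE 0.22) in limma went to 0.48 (SE 0.16, adjusted p = 0.0798) and 0.46 (SE 0.20, adjusted p = 0.182). The call for miR-484 ended without chow replicate 2 or 4 (adjusted p = 0.127 and 0.0561), and that for the predicted sequence without chow replicate 1 or 2 (0.0572 and 0.0713). Without HFrD replicate 1 or 4 the predicted sequence did not pass the filter, and without HFrD replicate 2 its log2 fold change was 1.76 (adjusted p = 0.0348). The call for miR-12182-3p ended without chow replicates 1, 2 and 4 (0.0797, 0.0991 and 0.0561) or HFrD replicate 3 (0.0644). For miR-671-3p it ended without chow replicates 2, 3 and 4 (0.155, 0.0512 and 0.111) or HFrD replicates 2, 3 and 4 (0.0567, 0.108 and 0.0910). Over the alternatives that tested each, adjusted p ran up to 0.127 for miR-484 and 0.0991 for miR-12182-3p (24 alternatives), 0.182 for miR-671-3p (23) and 0.0866 for the predicted sequence (19). The log2 fold change of the predicted sequence ran from 1.54 to 2.77 over its alternatives.

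**Figure D1:**
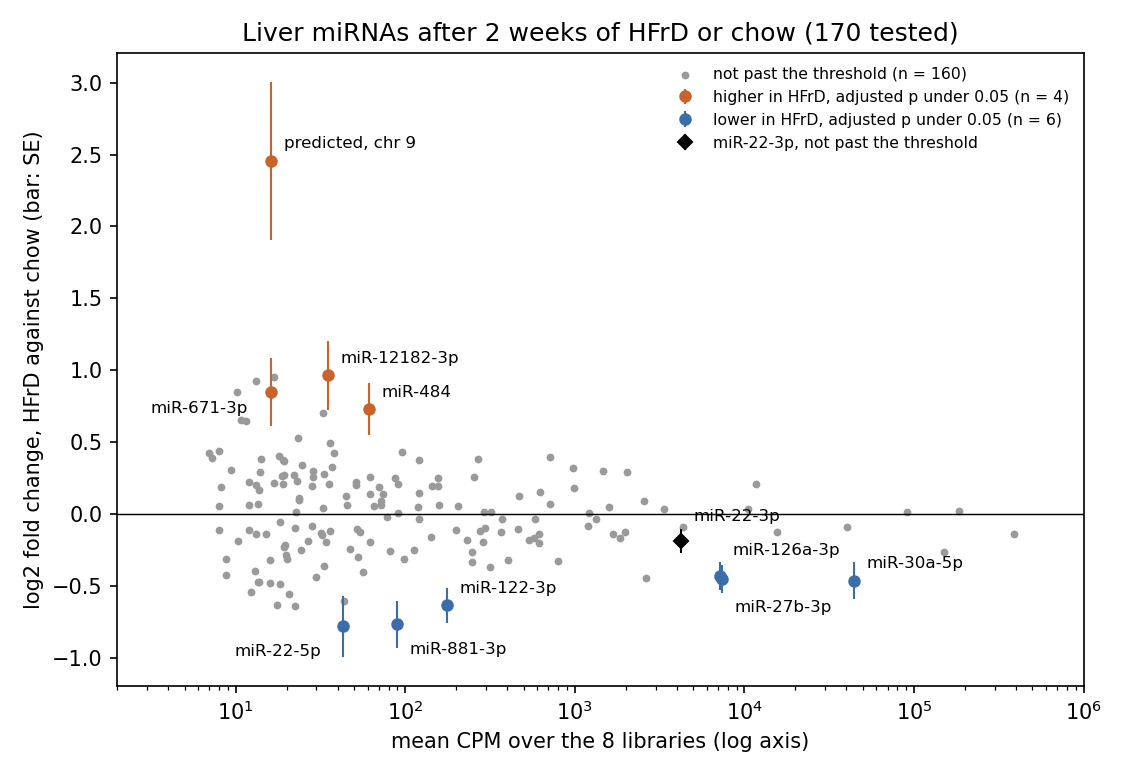
Log2 fold change of HFrD against chow (bars, SE) for the 170 tested miRNAs against their mean CPM over 8 libraries on a log axis. Coloured points are the 4 higher and 6 lower miRNAs with adjusted p under 0.05, from −0.78 for miR-22-5p to 2.46 for the predicted sequence, and the black diamond is miR-22-3p at −0.19.

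**Figure D2:**
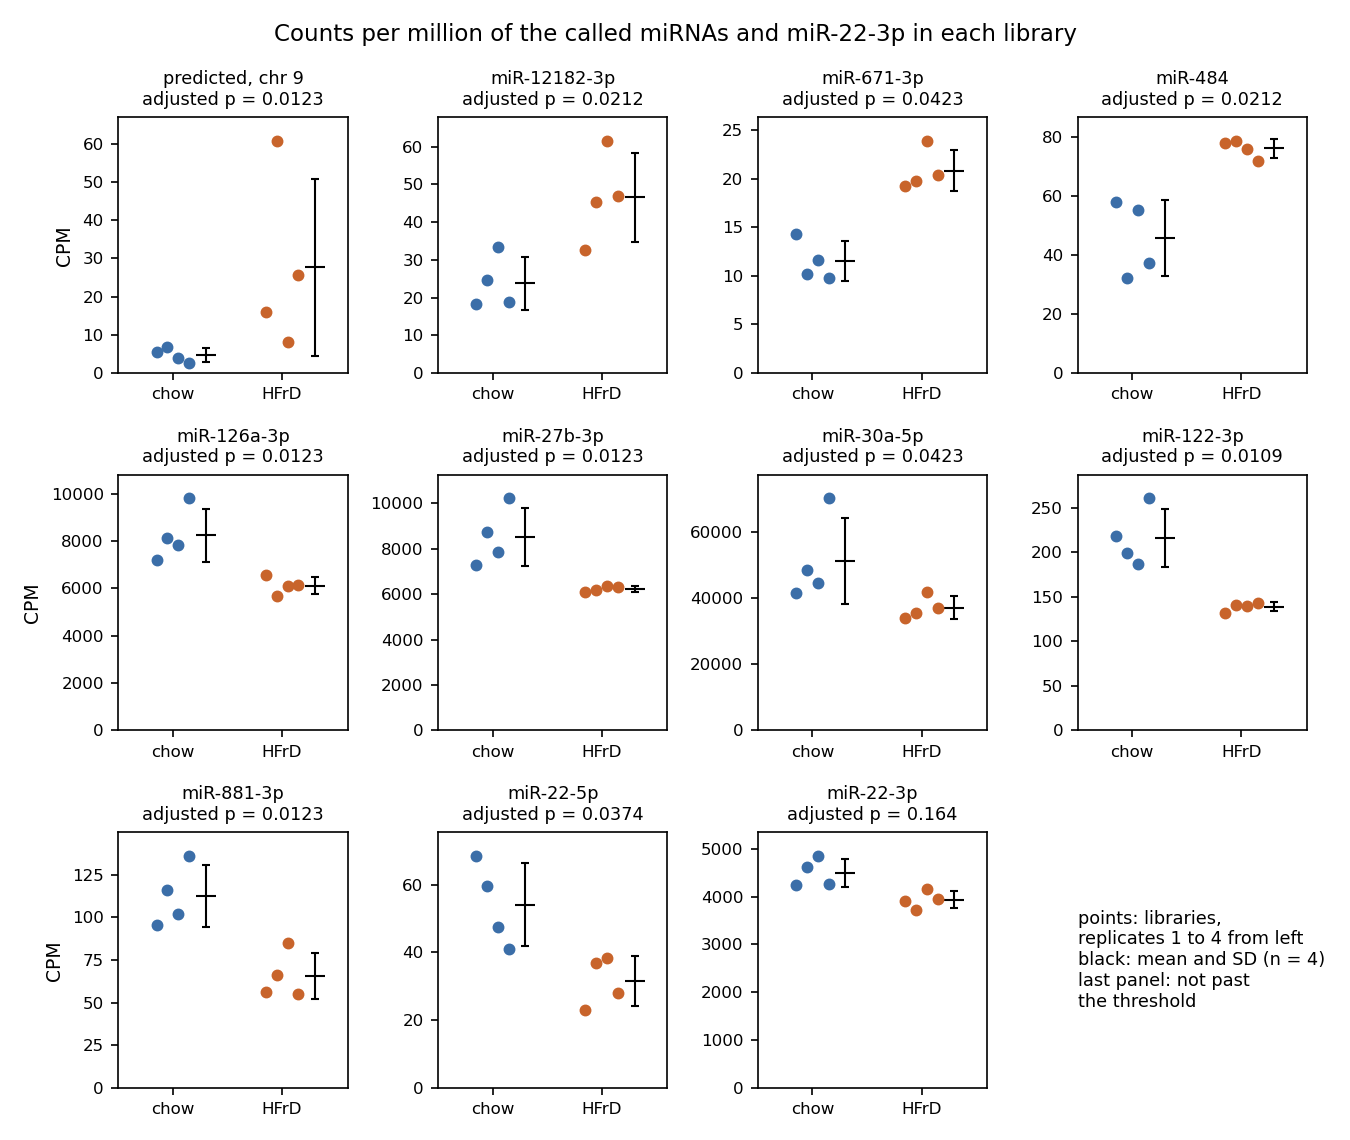
CPM in each library (points, replicates 1 to 4 from left) with mean and SD (n = 4 per diet) for the 10 changed miRNAs and miR-22-3p, on axes that start at 0. In this TMM-scaled CPM, groups do not overlap for 8 of the 10, miR-12182-3p and miR-30a-5p being the exceptions.

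In all, edgeR called 10 of 170 miRNAs, and 40 had an unadjusted p under 0.05, of which 22 were higher and 18 lower in HFrD. In 24 of the 170 (14.1%) the groups did not overlap in TMM-scaled CPM, against 2.86% by chance. The median log2 fold change of all tested miRNAs was 0.01 with TMM factors. With library totals it was 0.13 and 23 miRNAs were called, 17 higher and 6 lower, among them the same 10. With upper quartile factors edgeR called 1, the predicted sequence, limma on the authors' normalized score called 3, and edgeR without a filter 22. Leaving out the predicted sequences, an alternative chosen after the data were seen, gave 17, of which 9 were among the 10. Without 1 library at a time, 1 miRNA (without chow replicate 2) to 17 (without chow replicate 3) were called, and 6 without HFrD replicate 4. Only miR-122-3p was called whichever library was left out. Chow replicate 4 stood apart from the other chow libraries on the first principal component (37.4% of the variance), at −5.14 against −1.69 to −0.52, with the HFrD libraries above 0, up to 2.69. Without it 7 miRNAs were called, 6 of them among the 10.

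Further miRNAs fell short of the threshold. miR-183-5p had a log2 fold change of 0.43 (SE 0.13, adjusted p = 0.0566), miR-148b-3p 0.30 (SE 0.091, adjusted p = 0.0566) and miR-191-5p 0.38 (SE 0.12, adjusted p = 0.0566), each with groups that did not overlap. The values were 0.70 (SE 0.22, adjusted p = 0.0566) for miR-27a-5p, 0.95 (SE 0.30, adjusted p = 0.0586) for miR-1964-3p and 0.32 (SE 0.10, adjusted p = 0.0586) for miR-378a-3p, which is encoded within the metabolic coactivator gene Ppargc1b. On the lower side, miR-20a-5p had −0.37 (SE 0.12, adjusted p = 0.0566), miR-16-5p −0.61 (SE 0.20, adjusted p = 0.0588), miR-24-3p −0.32 (SE 0.12, adjusted p = 0.0953) and miR-3068-5p −0.64 (SE 0.23, adjusted p = 0.0953). Of the most abundant miRNAs, miR-148a-3p (log2 fold change −0.14, SE 0.091), miR-21a-5p (0.02, SE 0.12) and miR-192-5p (0.01, SE 0.085) did not pass, with adjusted p of 0.396, 0.928 and 0.936, and the sign of miR-21a-5p and miR-192-5p depended on the filter.

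None of the 16 lists that could be tested passed the threshold with camera, with a preset or an estimated correlation, or with fry, and 1 had an unadjusted p under 0.05. That was the endothelial list (7 members, median −0.18), with an adjusted p of 0.568, and of 0.901 with an estimated correlation. Of its members miR-126a-3p fell, and 6 did not pass, among them miR-10a-5p (−0.20, adjusted p = 0.175) and miR-24-3p. Adjusted over the list alone, miR-126a-3p and miR-24-3p passed as lower. Such an adjustment does not allow for the number of lists, and its verdict depends on the list. For miR-24-3p the adjusted p was 0.0426 in the endothelial list and 0.0724 in the lipid list. A 21-base form of miR-24-3p, listed as a predicted miRNA at 373 CPM against 406 CPM, was at −0.04 (SE 0.12, adjusted p = 0.823, edgeR). In the hepatocyte list (10 members, median −0.12, adjusted p = 0.568), miR-122-3p and miR-30a-5p fell and 8 did not pass, among them miR-148a-3p and miR-21a-5p. Adjusted over the list alone, 3 passed as lower, miR-122-5p being the other one (adjusted p = 0.0483, against 0.0724 in the lipid list). The median of the hepatocyte list ran from −0.17 to 0.01 over the alternatives. In the miR-30 family (9 members, median −0.16, adjusted p = 0.734), miR-30a-5p fell, also adjusted over the list alone. The rest did not pass, with −0.45 (SE 0.17, adjusted p = 0.113) for miR-30e-5p and 0.03 (SE 0.086, adjusted p = 0.801) for miR-30c-5p. Without chow replicate 4, miR-30e-5p was at −0.21.

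In the lipid and sterol list (25 members, median 0.06, adjusted p = 0.734), miR-27b-3p fell and 24 did not pass, among them miR-148a-3p and miR-122-5p. Adjusted over the list alone, miR-378a-3p and miR-183-5p passed as higher and miR-27b-3p as lower. By that adjustment miR-378a-3p did not pass in the insulin and glucose list (adjusted p = 0.0527, against 0.0488). In the insulin and glucose list (18 members, median 0.05, adjusted p = 0.734), miR-126a-3p fell, also adjusted over the list alone, and 17 did not pass, among them miR-21a-5p and miR-26a-5p (0.03, SE 0.088). No member passed in the list of fibrosis and inflammation in fatty liver (18 members, median 0.01, adjusted p = 0.734), whose most abundant members are miR-21a-5p and miR-192-5p, nor adjusted over the list alone. The same held for the stellate cell and fibroblast list (9 members, median −0.10, adjusted p = 0.734), with miR-143-3p at −0.09 (SE 0.097) and miR-152-3p at −0.33 (SE 0.14), or −0.15 without chow replicate 4. It held for the erythroid list (4 members, median 0.19, adjusted p = 0.734), with miR-451a at 0.06 (SE 0.23) and miR-486a-5p at 0.25 (SE 0.25). It held for the p53-regulated list (6 members, median −0.05, adjusted p = 0.839) and the hypoxia list (7 members, median 0.01, adjusted p = 0.839), whose most abundant members are miR-192-5p and miR-143-3p in the first and miR-21a-5p and miR-146a-5p in the second.

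Adjusted over the list alone, miR-183-5p was the only member higher in the biliary list (10 members, median −0.13, adjusted p = 0.986), and miR-30e-5p and miR-200a-3p (−0.20, SE 0.16) did not pass. In the miR-17 to miR-92 clusters (7 members, median −0.26, adjusted p = 0.734), miR-25-3p (0.29, SE 0.11) was higher and miR-20a-5p lower adjusted over the list alone, and neither passed over all miRNAs. In the miR-15 and miR-16 family (7 members, median 0.17, adjusted p = 0.734), miR-322-3p was at 0.42 (SE 0.20). There miR-16-5p passed as lower adjusted over the list alone (adjusted p = 0.0436, against 0.112 in the fibrosis list). The let-7 family (9 members, median 0.05, adjusted p = 0.839), with let-7g-5p at −0.09 (SE 0.080) and let-7f-5p at −0.13 (SE 0.081), had no member past the threshold by either adjustment. Nor had the miR-29 family (3 members, median 0.00, adjusted p = 0.734), with miR-29a-3p at 0.07 (SE 0.13) and miR-29b-3p at −0.48 (SE 0.25), or the Dlk1-Dio3 cluster (6 members, median −0.20, adjusted p = 0.734), with miR-379-5p at −0.11 (SE 0.12) and miR-127-3p at 0.01 (SE 0.14). The median and the mean differed in sign in the fibrosis, hypoxia, p53 and miR-29 lists, and camera and fry differed in direction in the biliary list. Taken for change in either direction, fry passed 6 lists (hepatocyte, lipid, insulin, endothelial, biliary and let-7), a test that does not compare a list with other miRNAs. Among the examples, the sign of let-7g-5p, miR-143-3p and miR-379-5p turned with library totals, that of miR-26a-5p, miR-30c-5p, miR-127-3p and miR-451a with a stricter filter, that of let-7f-5p and miR-486a-5p with the GC correction, and that of miR-29a-3p when a library was left out.

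**Figure D3:**
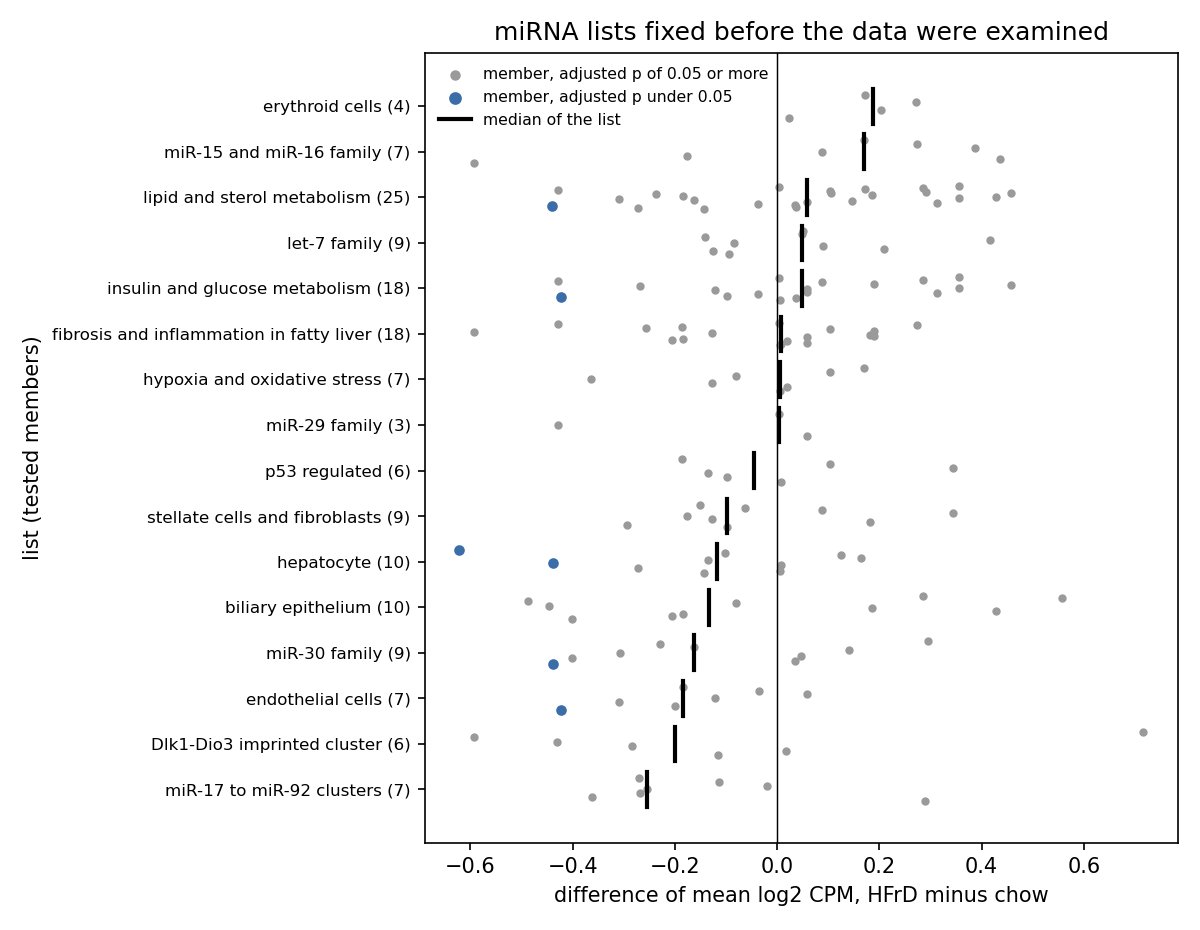
Difference of mean log2 CPM, HFrD minus chow, for each tested member (points) of the 16 lists, with the median as a black bar. Blue points are members with adjusted p under 0.05, which lie below 0 in each list that has any, and list medians run from −0.26 to 0.19.

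The lists for myeloid, lymphoid, muscle, and pancreas and neuroendocrine miRNAs and the miR-378 family had fewer than 3 members past the filter and were not tested. Of the myeloid list, 2 members passed the filter, miR-146a-5p (log2 fold change 0.01, SE 0.17, with a sign that turned under the stricter filter) and miR-146b-5p (−0.28, SE 0.21), with adjusted p of 0.954 and 0.466. The others that passed it were miR-150-5p (0.06, SE 0.29) and miR-181a-5p (0.19, SE 0.19) of the lymphoid list, miR-1a-3p (−0.17, SE 0.11) and miR-206-3p (−0.24, SE 0.17) of the muscle list, and miR-7a-5p (−0.27, SE 0.11) of the pancreas and neuroendocrine list. Of the miR-378 family they were miR-378a-3p and miR-378a-5p (0.49, SE 0.21), and none of these had an adjusted p under 0.05.

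The balance of the hairpin arms did not pass the threshold for any of 21 hairpins in limma, and 4 had an unadjusted p under 0.05. The 3 with the smallest p were miR-3068, whose log2 ratio of the 5p to the 3p arm went from 0.70 ± 0.32 to −0.24 ± 0.57 (SD, n = 4 each; adjusted p = 0.111), miR-152, from −4.19 ± 0.25 to −3.67 ± 0.20 (adjusted p = 0.219), and miR-22, from −6.39 ± 0.35 to −6.97 ± 0.34 (adjusted p = 0.219). For miR-22 the difference was −0.58 (SE 0.24), so that the fall of miR-22-5p was not shown to be larger than that of miR-22-3p. Without HFrD replicate 1, the miR-3068 ratio passed (difference −1.18, adjusted p = 0.0144).

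The composition of the libraries was compared in 8 measures, and none passed after adjustment. With a smallest exact permutation p of 0.0286, a single measure among 8 could not fall below an adjusted p of 0.229. Over library totals, the number of miRNAs with at least 10 CPM was 154 ± 1.71 (SD, n = 4) in chow and 162 ± 3.10 (SD, n = 4) in HFrD. It ran from 152 to 156 against 158 to 165, with no overlap (exact permutation p = 0.0286, adjusted p = 0.229). The erythroid miRNAs held 0.00968% ± 0.000883 of the counts in chow and 0.0119% ± 0.00365 in HFrD (exact permutation p = 0.229, adjusted p = 0.610), and without HFrD replicate 2 the difference went from 0.00220 to 0.000448. For muscle miRNAs the shares were 0.0631% ± 0.00924 and 0.0607% ± 0.00528 (exact permutation p = 0.771), and for pancreas and neuroendocrine miRNAs 0.0265% ± 0.00199 and 0.0242% ± 0.00352 (exact permutation p = 0.343). The exact permutation p was 0.514 for the total count, 0.0857 for the number of sequences listed, 0.714 for the share of miR-148a-3p and 0.400 for the share of the 10 most abundant miRNAs.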

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

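The tests on the GC-rich pair and both tests on the predicted sequence of chromosome 9 were chosen after the result was seen, and the tests on chow replicate 4 were chosen after its place on the principal components had been seen.

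Among 104 groups of 4 samples tested for a single sample far from the others, 4 had one, against 5.2 from chance. In chow, miR-24-3p was at 570 CPM in replicate 4 against 397 to 423 CPM in the other replicates. In HFrD, it was at 378 CPM in replicate 1 against 354 to 356 CPM. miR-192-5p was at 84061 CPM in chow replicate 1 against 92140 to 93201 CPM. miR-322-3p was at 48.8 CPM in HFrD replicate 2 against 41.5 to 42.3 CPM.

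The first pattern is the set of 10 sequences called between the diets. Of the 35 splits of the 8 libraries into 4 and 4, only the real one, 1 of 35, gave as many (10, against 0 in each of the other splits). That share is under 0.05 and is the smallest these splits can give. Each of the other splits mixes the diets, so a diet difference adds to its spread. Splits were counted with the main fit alone, and the count fell to 1 under some alternatives. A chance division of the libraries is thus less likely but not excluded. Against chow replicate 4 as the whole cause, the 10 kept most of their log2 fold change without that library. Their median share was 0.876 (SE 0.0190, lowest 0.646), although calls were lost. With library totals the median share was 0.853 (SE 0.0896, lowest 0.690). Library totals moved the median of all log2 fold changes from 0.01 to 0.13, so that called falls shrank and called rises grew. The smallest called change was 0.43, so most of it could hardly be lost, and this share does not decide on scaling. Upper quartile factors, with a median share of 0.854 (lowest 0.704), ended 9 of the 10 calls. The SEs of median shares in this paragraph treat the 10 miRNAs as independent. They come from the same libraries, so these SEs understate the error. Log2 fold changes of all tested miRNAs went with GC content (r = 0.319 across miRNAs, which are not independent), and although the 10 kept a median share of 0.963 (SE 0.0513) after a GC trend was removed, miR-122-3p kept 0.797 and miR-881-3p 0.836, and miR-484 and miR-671-3p a mean of 0.611 (0.590 to 0.633), their calls ending because the fold shrank from 0.76 (SE 0.18) to 0.48 (SE 0.16) and from 0.79 (SE 0.22) to 0.46 (SE 0.20). For this pair diet and yield cannot be told apart, since the trend itself goes with diet, and the diet, a shift in cell types and any handling that followed diet, of which the labels say nothing, stay open and untested.

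The second pattern is that chow replicate 4 lay apart from the other chow libraries. Its deviation from them had a covariance of −0.0151 with the difference of HFrD from them, across the 170 tested miRNAs, which are not independent replicates (r = −0.105). In 100 simulations without such a deviation and without a diet difference, the covariance averaged 0.0299 and ranged from 0.0132 to 0.0518. Chow replicate 3 left that range on the other side, at 0.0710, so that the range understates the spread between libraries. Chow replicate 4 was the only one of the 8 with a negative value, and its deviation may run partly along the diet difference, away from HFrD. Its deviation also went with GC content (r = −0.284, the largest of the 8 in size). That is opposite in sign to the log2 fold changes between diets (r = 0.319), which include this library. Whether the animal, the tissue, its handling or a yield that depends on GC content differed was not tested.

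The third pattern is the rise of the predicted sequence of chromosome 9, from counts of 3 to 8 in chow to 13 to 71 in HFrD. Since it lies within 18S ribosomal RNA, a candidate explanation is that fragments of that RNA were more abundant in HFrD libraries. Only 1 other listed sequence lies there, with 3 counts in chow and 7 in HFrD (2.23-fold in mean CPM, exact permutation p = 0.371; ratio of pooled rates 2.18, exact 95% interval from counting 0.497 to 13.0), too few to decide. The 32 predicted sequences that match longer transcripts, that sequence among them, summed to 12.9 ± 5.47 CPM in chow and 22.2 ± 9.98 CPM in HFrD (SD, n = 4 each), a 1.72-fold difference on 65 and 117 counts (exact permutation p = 0.114). Both comparisons used CPM over library totals. Carry-over of ribosomal or other RNA, a true miRNA and a change with diet cannot be told apart on these counts.

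No list and no arm ratio passed, so that 35 of 35 splits give at least as many whatever the data, and these comparisons say nothing about chance. Splits other than the real one gave up to 3 lists and up to 1 arm ratio.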

How the results depend on the processing

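The fits without predicted sequences, with an entry for each name, with blank cells as 1 count and with limma on log2 CPM with and without GC correction were chosen after the data were seen. Of the 24 alternatives, 16 kept the count of changed miRNAs within 1.5 times the 10 reported. It was 23 with library totals, 1 with upper quartile factors, 22 without a filter, 3 with limma on the authors' normalized values and 17 with the predicted sequences left out, and from 1 to 17 with each library left out in turn. Library totals and upper quartile factors moved the median of all log2 fold changes to 0.13 and 0.12, and the filters changed how many miRNAs were tested (443 with none, 160 with the stricter one), while the cause of the other differences was not tested. No pairing by replicate number was seen, as 2 of 8 libraries were closest to their own number. Correlations between samples of the same number ran from −0.0996 to 0.145, which does not exclude a weak pairing. With the replicate block 15 miRNAs changed, all 10 of the reported ones among them, and miR-22-5p was at −0.78 (adjusted p = 0.0152).

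miR-22-5p kept its direction under all 24 alternatives and its side of the threshold under 17. It was at −0.68 with upper quartile factors, −0.77 with DESeq2 and −0.60 with limma on the authors' normalized values, none past the threshold, and between −0.92 and −0.63 with each library left out; the cause was not tested. miR-22-3p was not past the threshold and below 0 under all 24 (−0.25 to −0.07). No list passed under any of 13 alternatives. Arm ratios changed numbered 0 to 1 with each library left out, miR-3068 being the exception, and 0 otherwise.

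Signs turned for some miRNAs that were not past the threshold. With library totals, let-7g-5p was at 0.027, miR-143-3p at 0.033 and miR-379-5p at 0.0082. With upper quartile factors, let-7g-5p was at 0.013 and miR-143-3p at 0.0044. With limma on the authors' normalized values, let-7g-5p was at 0.027, miR-143-3p at 0.024 and miR-379-5p at 0.00066. With the stricter filter, which moved the median of all miRNAs to −0.05, miR-21a-5p was at −0.036, miR-192-5p at −0.047, miR-127-3p at −0.050, miR-146a-5p at −0.030, miR-26a-5p at −0.026, miR-30c-5p at −0.022 and miR-451a at −0.00066. With limma-voom miR-451a was at −0.014. With GC correction miR-192-5p was at −0.016, let-7f-5p at 0.00014, miR-127-3p at −0.19 and miR-486a-5p at −0.076. The cause was not tested.

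With each library left out, the range was −0.088 to 0.15 for miR-21a-5p, −0.048 to 0.057 for miR-192-5p, −0.091 to 0.098 for miR-127-3p, −0.11 to 0.18 for miR-146a-5p, −0.048 to 0.090 for miR-26a-5p, −0.014 to 0.21 for miR-29a-3p, −0.0050 to 0.077 for miR-30c-5p, −0.19 to 0.23 for miR-451a and −0.038 to 0.40 for miR-486a-5p. List medians ranged from −0.21 to −0.075 (list: biliary epithelium), −0.18 to −0.034 (list: stellate cells and fibroblasts), 0.0028 to 0.058 (list: let-7 family), −0.068 to 0.0044 (list: p53 regulated) and −0.090 to 0.045 (list: hypoxia and oxidative stress). The medians of most other lists moved as much: −0.31 to −0.0048 (list: miR-30 family), −0.32 to −0.088 (list: miR-17 to miR-92 clusters), 0.019 to 0.29 (list: erythroid cells), −0.40 to −0.15 (list: Dlk1-Dio3 imprinted cluster), 0.073 to 0.24 (list: miR-15 and miR-16 family), −0.14 to −0.053 (list: hepatocyte) and 0.030 to 0.081 (list: lipid and sterol metabolism). Medians took both signs from −0.023 to 0.074 (list: insulin and glucose metabolism), −0.054 to 0.028 (list: fibrosis and inflammation in fatty liver) and −0.14 to 0.094 (list: miR-29 family). The range was −0.18 to −0.029 for miR-143-3p, −0.44 to −0.15 for miR-152-3p, −0.57 to −0.21 for miR-30e-5p, −0.35 to −0.067 for miR-200a-3p, −0.18 to −0.020 for miR-379-5p, −0.12 to −0.044 for let-7g-5p and −0.19 to −0.072 for miR-148a-3p. The test direction of the list: biliary epithelium turned in 6 of 13 alternatives while its median stayed below 0: with fry (median −0.13), with the stricter filter (median −0.19) and without chow replicate 1 or 4 or HFrD replicate 2 or 4. It also turned for the stellate list without HFrD replicate 3, let-7 without chow replicate 4, p53 without HFrD replicate 1 and hypoxia without chow replicate 4 or HFrD replicate 1. HFrD minus chow ranged from −2890 to 169777 counts (composition: total count), −1.02 to 0.376 (composition: percent in the most abundant miRNA), −0.00601 to 0.00132 (composition: percent in the muscle list), 0.000448 to 0.00313 (composition: percent in the erythroid list), −0.276 to −0.0308 (composition: percent in the 10 most abundant) and −0.00335 to −0.000784 (composition: percent in the pancreas and neuroendocrine list).

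Depth limits the miRNAs below about 10 CPM, where a count is a large part of the value, and 273 sequences were not tested. Changes of 1.5-fold were recovered in 63.5% of simulated cases with 60 of 170 miRNAs changed, and recovery would be lower with fewer changed. Thus miRNAs not called may include some that changed by such amounts.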

Other observations

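The test on sequences matching Scd1 and the choice of the neighbours and length variants described here were made after the values were seen.

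miRNAs that share a cluster did not all have values of the same sign. Of the cluster of miR-27b-3p, miR-23b-3p had a log2 fold change of 0.06 and miR-24-3p, which a second cluster also encodes, −0.32, neither past the threshold. miR-881-3p belongs to a group of 8 sequences from 7 genes on chromosome X between 66792595 and 66814025, of which it held 914 counts and miR-871-3p 166. Over library totals, the 7 sequences other than miR-881-3p summed to 23.5 ± 5.22 CPM in chow and 21.1 ± 3.79 CPM in HFrD (SD, n = 4 each; exact permutation p = 0.486). The CPM of miR-881-3p above are TMM-scaled. TMM factors averaged higher in HFrD (1.05 against 0.959 in chow), so that TMM scaling would make the fall of these 7 larger. miR-871-3p had a log2 fold change of −0.32 (adjusted p = 0.435, edgeR), and the difference between miR-881-3p and its neighbours was not tested.

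miR-24-3p was listed at its full length of 22 bases (UGGCUCAGUUCAGCAGGAACAG) and, as a predicted miRNA, at 21 bases (UGGCUCAGUUCAGCAGGAACA). The log2 fold change was −0.32 (SE 0.12) for the longer form and −0.04 (SE 0.12, adjusted p = 0.823, edgeR) for the shorter. The ratio of the longer to the shorter form was 1.20 ± 0.15 in chow and 0.994 ± 0.154 in HFrD (SD, n = 4 each; exact permutation p = 0.114). The 66 predicted sequences held 0.0555% ± 0.00387 of the counts in chow and 0.0646% ± 0.00186 in HFrD (SD, n = 4 each; exact permutation p = 0.0286, unadjusted). Of them, 32 matched longer transcripts, 2 a miRNA gene, 6 another small RNA gene and 26 none in sense. The sequence of chromosome 9 within 18S ribosomal RNA is among these 26, and the other sequence there is among the 32.

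Among the predicted sequences, 2 match Scd1, the gene of a lipogenic enzyme. A hypothesis was that fragments of its transcript follow diet. Their counts were 0 in all chow libraries and 0, 13, 2 and 8 in HFrD replicates 1 to 4, with values below 2 not listed. For 0 against 23 counts the exact permutation p was 0.143. With counts only in HFrD replicates 2, 3 and 4, no split could give a smaller p. The test could thus not decide, and so few counts leave the hypothesis open.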
